A study of Homo sapiens with 12 samples.

How the data were processed

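Gene expression was measured in HL60 cells that carried an EVI1 expression vector or an empty vector, after 24 h in 1 µM ATRA or in DMSO. Per the labels' protocols, total RNA was isolated with RNeasy from cells grown in RPMI with 10% FCS, and 250 ng was amplified and biotin-labelled with the 3′ IVT Express protocol. The 12 arrays form 4 groups of 3. The series design states 3 biological replicates, and the labels do not say further how the cultures were kept apart, so p-values treat the arrays as independent cultures.

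The deposited values are log2 signals on 54675 probe sets of the Affymetrix U133 Plus 2.0 array. Per the submitters' processing notes, RMA in Affymetrix Expression Console 1.3 made them. They run from 2.0 to 14.46 with 0 missing, the array medians lie between 5.09 and 5.14, and the mean correlation of each array with the others of its group lies between 0.9897 and 0.9978. They were used as deposited. No genome build is named with them, so no coordinates are given. Raw intensity files were not used here.

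Probe sets were named by the annotation table of the array, with gene symbols looked up by Entrez identifier in a RefSeq table, which changed 0 symbols and matched 41043 probe sets. Of all probe sets, 41097 name a single gene, 1801 name several and 11777 name none; the 62 control probe sets of the array are counted among these. The 41097 cover 19775 genes, of which 10523 have more than 1 probe set, and each gene was represented by the probe set with the highest mean over all arrays. No intensity filter was used. Some listed genes lie only on probe sets with several names or no name and were not analysed here.

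The following choices were made before the data were examined: the tests, the alternatives apart from 6 named below, the gene lists and the rule for naming genes. A 4-group linear model with 8 residual degrees of freedom was fitted in R 4.3.3 with limma 3.58.1, with empirical Bayes moderation, and Benjamini-Hochberg adjustment over all genes within each of 5 contrasts, at 0.05. The contrasts were ATRA against DMSO in vector cells and in EVI1 cells, the difference of these responses, and EVI1 against vector cells in DMSO and in ATRA. Counts are also given at a change of at least 2-fold. The overlap of the responses was set against the number expected for independent calls. The two-sided Fisher test fixed for it gives a p too small to be represented, so one-sided values are given as logarithms. The share of responsive genes with the larger response in EVI1 cells used genes called at 2-fold by the average ATRA effect, which does not depend on the difference between lines, and was tested by a two-sided exact permutation of the line labels within DMSO and within ATRA. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

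The 27 gene lists covered retinoid genes, neutrophil receptors, secondary and tertiary granule proteins, NADPH oxidase, primary granule proteins, monocyte markers, myeloid transcription factors, stem and progenitor genes, genes reported as EVI1 targets or partners, erythroid, megakaryocyte, eosinophil, basophil and mast cell, lymphoid, epithelial and fibroblast genes, mitosis, DNA replication, cell cycle inhibitors, MYC targets, interferon-stimulated genes, chemokines, apoptosis regulators, class II antigen presentation, the TGF-beta pathway, cholesterol synthesis, the unfolded protein and stress response, glycolysis and hypoxia, and housekeeping genes. They were written from general knowledge, share some members, and were tested with limma's camera at a preset correlation of 0.01, with adjustment over the 27 lists within a contrast, and again with the correlation estimated from the data. Camera compares the members of a list with all other genes, and does not ask whether another set of cultures would show the same shift.

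Named genes are MECOM, the 10 largest rises and 10 largest falls per contrast among called genes whose arrays did not overlap between the groups, up to 4 members per described list with the largest changes, and CYP26A1, DHRS3, CD38, ITGAM, ITGAX, CEBPE, MPO, MYC, CD14 and GATA2 in every contrast. Genes outside this rule are said to have been named after their values were seen.

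The labels number the replicates 1 to 3 in every group, so it was checked whether the numbers pair the arrays. Deviations from the group means correlated at 0.109 to 0.691 in all 18 pairs of arrays with the same number, and at -0.614 to 0.421 in the 36 pairs with different numbers. The rule fixed for this, all 18 being above 0.1, was met, by the data and not the labels. It can be met where number 1 alone stands apart, since all pairs of numbers 2 and 3 also correlated positively (0.017 to 0.421). EVI1 DMSO replicate 3 was closer to EVI1 ATRA replicate 2 (0.421) than to EVI1 ATRA replicate 3 (0.35). The data thus set number 1 apart and do not settle whether numbers 2 and 3 pair the arrays. Of the 12 arrays, 6 were closest to their own number in every other group. The fit without the block is the main one, and values with replicate number as a block are given beside the counts they move by more than 1.5 times and the calls they change among the genes and lists described in that comparison; calls of other genes that the naming rule covers enter the closing section as a number.

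Alternatives were the mean of all probe sets per gene, every probe set tested, genes above the median level, arrays centred on their median, scaled to the housekeeping list or quantile normalized once more, an intensity trend with a robust prior, array weights, a fit to the compared groups alone, the replicate block, an unmoderated test with pooled variance, and leaving out each array in turn. For the share of responsive genes, other ways of choosing the genes were tried too. Chosen after seeing the data were 6: leaving out both EVI1 arrays numbered 1, all 4 arrays numbered 1, both EVI1 arrays numbered 1 with the replicate block, the 20 genes that were 2-fold higher in vector replicate 1, culture as a random block, for which the estimated correlation was 0.261, and a permutation of list means that swaps the lines within each replicate number and treatment.

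The pipeline was tested on simulated data with 19775 genes, 100 of them changed 1.4-fold and 100 changed 2-fold. Of the 2-fold changes 97% and 86% were called for ATRA in vector and EVI1 cells, 76% for the difference of responses, and 90% and 91% for EVI1 in DMSO and in ATRA. Of the 1.4-fold changes 49%, 46%, 28%, 63% and 57% were called in the same order. False calls made up between 3.16% and 5.19% of all calls. The simulated noise was independent between genes and arrays, with no array standing apart, so fewer changes may be found on the real arrays. The permutation test of the share was run on 20 draws with 300 changed genes. With equal responses the median share was 50.2% and 1 draw fell under 0.05. With a response 1.5 times as strong in EVI1 cells the median share was 99.7%, the median extra change was 0.751, and p lay between 0.01 and 0.09 with a median of 0.0525, so 7 of 20 draws fell under 0.05. This test had low power in these draws. The simulated lines did not differ in DMSO, so relabelling the DMSO arrays changed the statistic little and many arrangements came close to the observed value. Since the draws held no line difference in DMSO, they do not show the power of the test on the real arrays. The same permutation applied to list means was not simulated.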

Results

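HL60 cells, a human promyelocytic leukaemia line, carried either an EVI1 construct or an empty vector and were kept for 24 h in 1 µM all-trans retinoic acid (ATRA) or in its solvent DMSO. EVI1 is a zinc finger transcription factor encoded at the MECOM locus, and ATRA is a ligand of the retinoic acid receptors that makes promyelocytic cells differentiate. RNA of each of the 4 combinations was measured on 3 Affymetrix U133 Plus 2.0 arrays, 12 arrays in all, with the replicates of each group numbered 1 to 3. The values are log2 RMA signals on 54675 probe sets, and 19775 genes were compared, each by its brightest probe set that names a single gene. The number of arrays limits the precision: the median standard error of a log2 difference between 2 groups was 0.101, and that of a difference between 2 responses was 0.143. Where a log2 difference is followed by ±, this is its standard error in the limma fit, without a block unless stated. There were n = 3 arrays per group, except where arrays were left out.

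The EVI1 label could not be checked from these arrays. The 5 probe sets of MECOM read between 2.62 and 3.46 on all 12 arrays, below the 25th percentile of every array, which lay between 3.61 and 3.69. The brightest of them averaged 3.25 ± 0.050 (SD, n = 3) in vector cells and 3.32 ± 0.091 in EVI1 cells in DMSO, a difference of 0.07 ± 0.09 with adjusted p = 0.876. In ATRA the difference was -0.06 ± 0.09 with adjusted p = 0.849. Over the 6 EVI1 and 6 vector arrays, two-sided exact permutation p-values of the 5 probe sets were 0.976, 0.297, 0.924, 1 and 0.206. The labels do not give the sequence of the construct, so signals at background from these probe sets do not show whether it was expressed.

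ATRA against DMSO in vector cells gives the response of HL60 cells without the EVI1 construct. The retinoid dehydrogenase DHRS3 rose 26.5-fold, by 4.73 ± 0.22 in log2 (adjusted p = 2.63e-07), and the ectoenzyme CD38 rose by 3.44 ± 0.14. PTGES, the prostaglandin E synthase, showed the largest rise, 51.9-fold (5.70 ± 0.28). After DHRS3 came the laminin-binding integrin chain ITGA6 (4.71 ± 0.32), the G protein subunit GNG2 (4.65 ± 0.30), the neutrophil granule glycoprotein CHI3L1 (4.34 ± 0.39), the Src family kinase FGR (4.30 ± 0.23), the lipid-presenting molecule CD1D (4.01 ± 0.09), the oxidase subunit NCF1 (3.88 ± 0.22) and the chemokine CCL2 (3.78 ± 0.60). Myeloid surface integrins rose as well, ITGAM by 2.47 ± 0.28 and ITGAX by 1.25 ± 0.19. IGLL1, the surrogate light chain, fell by 3.20 ± 0.28, the factor XIII A chain F13A1 fell by 3.10 ± 0.20, the caveola protein CAV1 fell by 2.80 ± 0.16, TENT5C fell by 2.75 ± 0.19, and the intermediate filament protein VIM fell by 2.68 ± 0.14. SHISA2, SERPINB10, DEPTOR, MICAL2 and LINC01215 fell by 2.53, 2.28, 2.21, 2.19 and 1.92.

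Of the genes fixed for every comparison, 3 encode transcription factors that changed in vector cells. GATA2, a factor of stem and progenitor cells, fell by 1.31 ± 0.16 (adjusted p = 0.000406). CEBPE, a factor of granulocyte maturation, rose by 0.92 ± 0.20 (adjusted p = 0.0109) and MYC fell by 0.65 ± 0.14 (adjusted p = 0.0114). The CEBPE call was lost without vector ATRA replicate 2 (adjusted p = 0.0516) and the MYC call without vector ATRA replicate 3 (0.0558). The scavenger receptor OLR1 rose by 3.66 ± 0.88 (adjusted p = 0.0199), a call lost without vector DMSO replicate 1 or 2 (0.065 and 0.0774) or vector ATRA replicate 2 or 3 (0.0745 and 0.0828). No change was called for the granule enzyme MPO (-0.10 ± 0.09), the monocyte receptor CD14 (0.09 ± 0.46) or the retinoic acid hydroxylase CYP26A1 (-0.12 ± 0.14). Every gene named here as risen or fallen had its 3 ATRA arrays on the same side of its 3 DMSO arrays. In all, 2029 of 19775 genes passed an adjusted p of 0.05 in limma, 919 up and 1110 down, and 299 of them changed at least 2-fold, 231 up and 68 down. The balance depended on scaling: 824 rose and 1245 fell with the arrays centred on their median, and 1022 rose and 943 fell with the arrays scaled to the housekeeping list. Without vector ATRA replicate 1 or 3 the count was 1342 or 1070, and without vector DMSO replicate 2 or 3 it was 1177 or 1337. With limma run on the 6 vector arrays alone it was 3522.

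Of the 27 lists of genes, 11 passed in vector cells. Of 34 retinoid receptors, enzymes and direct targets, 13 rose and 4 fell (13 and 5 adjusted over the list alone), among them DHRS3, CD38 and the repressor HIC1 (3.45 ± 0.24), with camera adjusted p = 0.000264 and adjusted p = 0.218 with an estimated correlation. Of 29 neutrophil surface receptors and adhesion molecules, 11 rose and 1 fell (13 and 2 adjusted over the list alone). ITGAM, ITGAX and the adhesion molecule PECAM1 (1.14 ± 0.15) rose, while the Fc receptor FCGR2A fell 2.47-fold (adjusted p = 0.00267); the list had adjusted p = 0.000631, and adjusted p = 0.1 with an estimated correlation. Of 25 secondary and tertiary granule proteins, 6 rose and 0 fell (7 and 0 adjusted over the list alone), at adjusted p = 0.000631 and adjusted p = 0.296 with an estimated correlation. The median of that list was 0.047. Risen members included CHI3L1, the lipoxygenase partner ALOX5AP (2.02 ± 0.22), CYBB (2.01 ± 0.19) and the cathepsin CTSZ (2.21 ± 0.37). Of these, ALOX5AP is not itself a granule protein, and CTSZ is a lysosomal protease in many cell types. Of 9 NADPH oxidase subunits and regulators, 4 rose, among them NCF1, CYBB and CYBA (0.66 ± 0.10), and 6 rose and 2 fell when adjusted over the list alone (adjusted p = 0.000121, and adjusted p = 0.234 with an estimated correlation). Of 26 monocyte and macrophage markers, 7 rose and 2 fell (8 and 3 adjusted over the list alone), with the lipid scavenger CD36 at 3.30 ± 0.22, the Fc receptor chain FCER1G at 1.18 ± 0.18 and the transcription factor KLF4 at -1.72 ± 0.11. That list had adjusted p = 0.0395, which became 0.0715 without vector ATRA replicate 1, 0.0719 without vector DMSO replicate 3 and 0.0679 without EVI1 ATRA replicate 1, and adjusted p = 0.234 with an estimated correlation.

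A further 6 lists passed in vector cells. Of 32 MYC targets and ribosome biogenesis genes, 0 rose and 14 fell (0 and 24 adjusted over the list alone), among them the spermidine synthase SRM (-0.67 ± 0.09) and the small subunit processome member RRP9 (-0.65 ± 0.10), at adjusted p = 2.6e-09 and adjusted p = 0.234 with an estimated correlation. Of 22 cell cycle inhibitors and exit genes, 8 rose and 2 fell (10 and 3 adjusted over the list alone), with ID1 at 2.50 ± 0.44 and the antiproliferative factor BTG1 at 1.20 ± 0.12 (adjusted p = 0.00834, and adjusted p = 0.271 with an estimated correlation). ID1, an inhibitor of differentiation factors, is not itself a cell cycle inhibitor. Of 50 interferon-stimulated genes, 15 rose and 2 fell (19 and 2 adjusted over the list alone): IFI6 rose by 2.74 ± 0.22, DDX60 by 1.19 ± 0.18 and the transcription factor IRF1 by 1.13 ± 0.10, while the proapoptotic XAF1 fell by 1.13 ± 0.12. Its adjusted p was 1.04e-08, and adjusted p = 0.1 with an estimated correlation. Of 37 chemokines, cytokines and NF-kB targets, 8 rose and 2 fell (11 and 3 adjusted over the list alone), with the chemokine receptor CCR1 at 2.75 ± 0.11 (adjusted p = 0.00851, and adjusted p = 0.624 with an estimated correlation). Of 29 TGF-beta pathway genes, 5 rose and 0 fell (8 and 0 adjusted over the list alone), with ID2 at 0.68 ± 0.10, at adjusted p = 0.00625 and adjusted p = 0.14 with an estimated correlation. Of 30 unfolded protein and integrated stress response genes, 2 rose and 9 fell (2 and 11 adjusted over the list alone), with the serine synthesis enzymes PSAT1 (-0.87 ± 0.09) and PHGDH (-0.86 ± 0.12) and the asparagine synthetase ASNS (-0.79 ± 0.15). The largest change of the list was a rise, that of SLC7A11 (1.44 ± 0.37, limma adjusted p = 0.0282). Its call was lost without any of the 6 vector arrays (0.0566 to 0.107). This list had adjusted p = 0.0281, which became 0.0602 and 0.0744 without vector DMSO replicates 1 and 2 and 0.0681 without vector ATRA replicate 3, and adjusted p = 0.624 with an estimated correlation.

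The other 16 lists did not pass in vector cells. Camera adjusted p-values were 0.142 for DNA replication and S phase genes (0 up and 2 down of 41), 0.184 for eosinophil, basophil and mast cell genes (0 and 2 of 18), 0.184 for apoptosis regulators (7 and 3 of 33), 0.228 for mitosis and G2/M genes (0 and 4 of 32) and 0.264 for genes reported as EVI1 targets or partners (6 and 4 of 36). They were 0.282 for primary granule proteins of promyelocytes (2 and 6 of 21), 0.409 for myeloid transcription factors (5 and 3 of 30), 0.409 for megakaryocyte genes (2 and 1 of 18), 0.409 for cholesterol synthesis (0 and 0 of 18) and 0.409 for glycolysis and hypoxia response (3 and 4 of 29). For housekeeping control genes the value was 0.632 (2 and 2 of 25), for class II antigen presentation 0.712 (0 and 0 of 15), for erythroid genes 0.897 (0 and 1 of 21), for epithelial and fibroblast genes 0.897 (0 and 1 of 25), for stem and progenitor cell genes 0.956 (2 and 3 of 26) and for lymphoid genes 0.97 (0 and 0 of 27). List median, list mean and camera direction differed in sign in 19 of the 135 list tests, and 0 of these 19 passed. In vector cells they were the myeloid transcription factor, stem cell, EVI1 target and megakaryocyte lists.

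**Figure D1:**
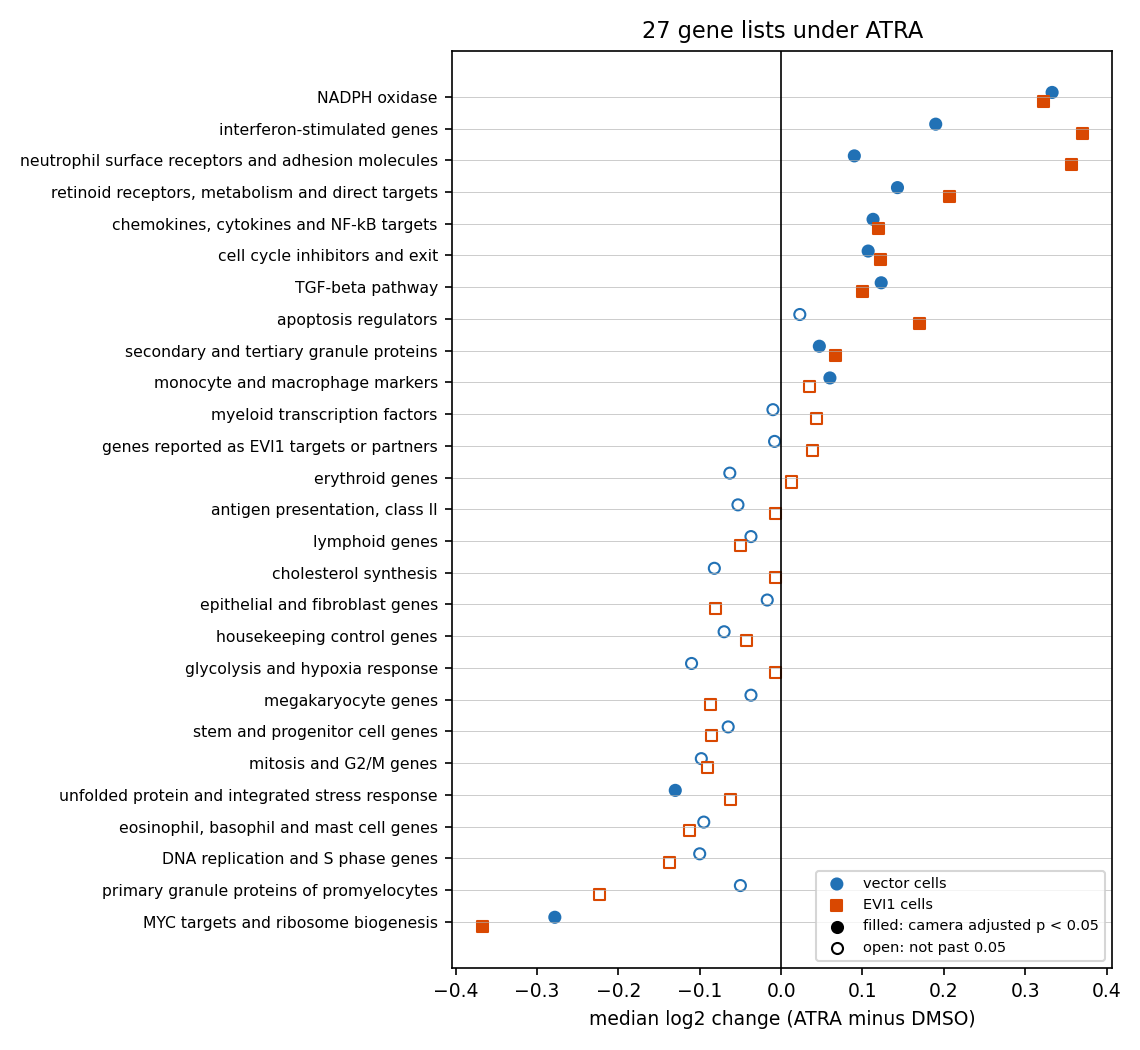
Median log2 change under ATRA (horizontal axis, ATRA minus DMSO) over the measured members of each of 27 gene lists, in vector cells (circles) and EVI1 cells (squares), filled where camera's adjusted p was below 0.05. MYC targets lay lowest at -0.28 in vector cells and -0.37 in EVI1 cells, and interferon-stimulated genes lay at 0.19 and 0.37.

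ATRA against DMSO in EVI1 cells gives the response with the construct. PTGES rose 41.9-fold (5.39 ± 0.28), DHRS3 25.3-fold (4.66 ± 0.22) and the scavenger receptor CD36 20.2-fold (4.34 ± 0.22, adjusted p = 5.29e-07). Other large rises were those of GNG2 (4.31 ± 0.30), the actin-associated protein PALLD (4.24 ± 0.37), the leukocyte receptor LILRA5 (4.17 ± 0.37), FGR (3.96 ± 0.23), CHI3L1 (3.86 ± 0.39), CD38 (3.69 ± 0.14) and ITGA6 (3.63 ± 0.32). TENT5C fell by 2.87 ± 0.19, IGLL1 fell by 2.75 ± 0.28, VIM fell by 2.54 ± 0.14, CAV1 fell by 2.43 ± 0.16 and DEPTOR fell by 2.27 ± 0.35. CAV1 averaged 3.66 in EVI1 cells in ATRA, near background. SERPINB10, DTNA, the BMP antagonist NOG, the interleukin receptor antagonist IL1RN and the glutamate transporter SLC1A3 fell by 2.00, 1.95, 1.94, 1.93 and 1.89.

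Of the same fixed genes in EVI1 cells, ITGAM rose by 2.41 ± 0.28 and ITGAX by 1.48 ± 0.19, GATA2 fell by 1.45 ± 0.16 (adjusted p = 0.000177) and MYC fell by 0.84 ± 0.14 (adjusted p = 0.00199). CEBPE rose by 0.78 ± 0.20 (adjusted p = 0.0227), a call lost without EVI1 ATRA replicate 2 or 3 (0.0923 and 0.0994) or EVI1 DMSO replicate 1 or 3 (0.0592 and 0.0563). CYP26A1 rose by 0.46 ± 0.14 (adjusted p = 0.0484), a call that leaving out any array but EVI1 ATRA replicate 1 or vector DMSO replicate 3 ended, with adjusted p between 0.0518 and 0.17. MPO had -0.23 ± 0.09 (adjusted p = 0.151, and 0.0398 with replicate number as a block) and CD14 had 0.43 ± 0.46 (adjusted p = 0.649). In all, 2437 genes passed, 1118 up and 1319 down, and 338 of them changed at least 2-fold, 256 up and 82 down. Without EVI1 DMSO replicate 2 the count was 1587, and without EVI1 ATRA replicate 3 it was 1513. With limma run on the 6 EVI1 arrays alone it was 824.

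The lists of EVI1 cells that passed included 9 of the 11 that passed in vector cells. Of the 34 retinoid genes, 14 rose and 3 fell (15 and 4 adjusted over the list alone), with DHRS3, ID1 (2.74 ± 0.44) and HIC1 (3.35 ± 0.24), at adjusted p = 9.78e-07 and adjusted p = 0.0921 with an estimated correlation. Of the 29 neutrophil receptors, 15 rose and 2 fell (15 and 3 adjusted over the list alone), with ITGAM, ITGAX and PECAM1 (1.16 ± 0.15), at adjusted p = 2.13e-05 and adjusted p = 0.036 with an estimated correlation. Of the 25 genes on the secondary and tertiary granule list, 8 rose and 1 fell (8 and 1 adjusted over the list alone), with a median of 0.067. Those that rose included CHI3L1, CYBB (2.04 ± 0.19) and ALOX5AP (1.90 ± 0.22), the last not itself a granule protein. The list had camera adjusted p = 0.00708, and adjusted p = 0.497 with an estimated correlation. Of the 9 NADPH oxidase genes, 5 rose and 0 fell by either adjustment, over all genes or adjusted over the list alone, with NCF1 at 3.55 ± 0.22 and CYBA at 0.80 ± 0.10 (adjusted p = 1.01e-05, and adjusted p = 0.19 with an estimated correlation). Of the 32 MYC targets and ribosome genes, 0 rose and 26 fell (0 and 27 adjusted over the list alone), with SRM at -0.81 ± 0.09, RRP9 at -0.72 ± 0.10 and NIP7 at -0.70 ± 0.09, at adjusted p = 1.14e-15 and adjusted p = 0.107 with an estimated correlation. Of the 50 interferon-stimulated genes, 19 rose and 1 fell (29 and 2 adjusted over the list alone), with IFI6 at 2.68 ± 0.22, DDX60 at 1.39 ± 0.18, IRF1 at 1.26 ± 0.10 and XAF1 at -1.20 ± 0.12, at adjusted p = 1.81e-15 and adjusted p = 0.036 with an estimated correlation. The neutrophil and interferon lists were the 2 of all 42 list calls that held with an estimated correlation.

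Further lists that passed in EVI1 cells were the following. Of the 22 cell cycle inhibitors and exit genes, 7 rose and 2 fell (9 and 3 adjusted over the list alone), with BTG1 at 1.38 ± 0.12 (adjusted p = 0.00314, and adjusted p = 0.222 with an estimated correlation). Of the 37 chemokines and NF-kB targets, 9 rose and 1 fell by either adjustment, over all genes or adjusted over the list alone, with CCR1 at 2.51 ± 0.11 (adjusted p = 0.000772, and adjusted p = 0.564 with an estimated correlation). CCL2, with 2.73 in log2, lost its call without EVI1 ATRA replicate 3 (0.0526). Of the 29 TGF-beta pathway genes, 6 rose and 1 fell (9 and 2 adjusted over the list alone), with ID2 at 0.70 ± 0.10 (adjusted p = 0.00847, and adjusted p = 0.107 with an estimated correlation). Of the 33 apoptosis regulators, 11 rose and 1 fell (13 and 4 adjusted over the list alone), with the survival factor BCL2A1 at 2.55 ± 0.41, BCL2 at -1.12 ± 0.11 and the caspase CASP9 at 0.91 ± 0.12. That list had adjusted p = 0.0456, and adjusted p = 0.689 with an estimated correlation. It was lost without EVI1 ATRA replicate 2 (0.0853) or 3 (0.195), EVI1 DMSO replicate 1 (0.197) or vector DMSO replicate 1 (0.0508) or 2 (0.0528). Its median turned from 0.17 to -0.02 without EVI1 DMSO replicate 2. BCL2A1 and BCL2 both act against apoptosis and moved in opposite directions. Monocyte markers (8 up and 2 down of 26) had adjusted p = 0.14, the unfolded protein and stress list (1 and 7 of 30) 0.612, and DNA replication genes (0 and 3 of 41) 0.0524, or 0.0291 with replicate number as a block. Without the block and with an estimated correlation, camera gave the DNA replication list adjusted p = 0.533. The remaining 14 lists had adjusted p between 0.121 and 0.982.

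Whether EVI1 changes the ATRA response, the question posed by the title of the series, was asked first by setting the 2 responses side by side. The genes that moved were largely shared: 751 genes rose and 865 fell in both lines, 1616 in all, where 52.0 and 74.0 would be shared if the calls were independent, and 0 genes were called in opposite directions. One-sided Fisher's exact tests gave log10 p of -892 for the genes up and -924 for the genes down. The 2 contrasts share no array, but they come from the same fit, with a shared estimate of the spread of each gene. Calls in the 2 lines are therefore not independent, and these p-values overstate the evidence for a shared response. With only the groups compared the number shared was lower, as given in the closing section. Of the 2850 genes called in either line, 2791 had the same sign in both, and across all genes the log2 changes had r = 0.881, with genes not being independent replicates. Without vector DMSO replicate 2 or vector ATRA replicate 3 the number shared was 1039 or 972.

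**Figure D2:**
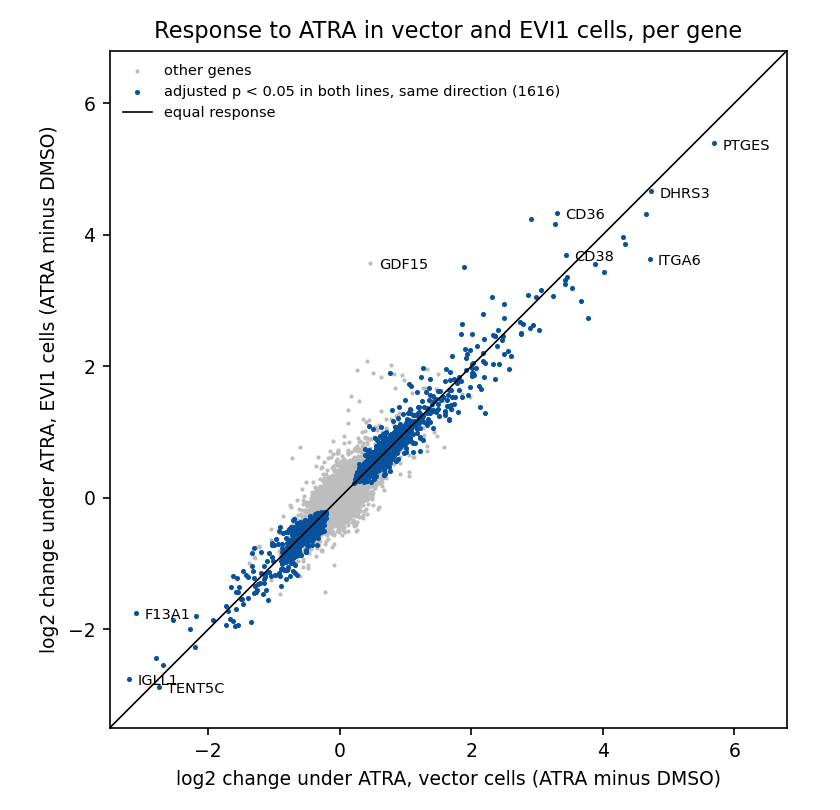
Log2 change under ATRA (ATRA minus DMSO) of each of 19775 genes in vector cells (horizontal axis) and EVI1 cells (vertical axis), with the 1616 genes called in both lines in the same direction in blue. PTGES lay at 5.70 and 5.39, and GDF15, called in EVI1 cells against vector cells in ATRA, lay above the line of equal response.

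The second measure was the share of ATRA-responsive genes with the larger response in EVI1 cells. Among 324 genes that changed at least 2-fold over both lines, 167 or 51.5% had the larger change in EVI1 cells, and the median extra change was 0.012 in log2. The median response was 1.39 in vector cells and 1.43 in EVI1 cells. A two-sided exact permutation test over 400 arrangements gave p = 0.96, with 0.005 the smallest it could give. By replicate number the share was 27.8%, 56.2% and 68.5%. It was 70.4% of 378 genes without both EVI1 arrays of replicate 1 (exact p = 0.51), and it ranged from 35.7% without EVI1 ATRA replicate 3 to 73.2% without EVI1 ATRA replicate 1. In simulated data in which EVI1 cells responded 1.5 times as strongly, this exact permutation test fell under 0.05 in only 7 of 20 draws, so p = 0.96 does not show that the responses were equal.

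The third measure tested the difference of the responses gene by gene. Differences among genes named here included those of GDF15, a stress-responsive TGF-beta family cytokine (3.10 ± 0.50, adjusted p = 0.507), PTX3, a secreted pattern recognition molecule (-1.21 ± 0.24, adjusted p = 0.999, with vector cells at background), ITGA6 (-1.08 ± 0.46) and CD36 (1.03 ± 0.31). CD38 had 0.25 ± 0.20, ITGAM -0.07, ITGAX 0.23, CEBPE -0.14, MYC -0.20, GATA2 -0.14, CD14 0.35, MPO -0.13, DHRS3 -0.07, MECOM -0.13 and CYP26A1 0.58 ± 0.19, each with adjusted p = 0.999. By limma 0 genes passed, and the count was also 0 with replicate number as a block and by the unmoderated test. Without EVI1 ATRA replicate 1 the count was 3. At an unadjusted limma p below 0.05 there were 628 genes, against 989 expected by chance. A number below 989 does not show equal responses. Without both EVI1 arrays numbered 1, an alternative chosen after seeing the data, it was 1532. In the self-test of this contrast 76% of genes altered 2-fold and 28% of those altered 1.4-fold were recovered. The simulated arrays had independent noise and none stood apart, so these shares may be too high for the real arrays. GDF15, at 3.10, was not called in the real data.

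Of the 27 lists, 3 passed in this contrast, all with 0 members called over all genes or adjusted over the list alone. MYC targets and ribosome biogenesis genes had a median difference of -0.11, with 1 of 32 members positive (camera adjusted p = 2.42e-05, and adjusted p = 0.675 with an estimated correlation). Their mean response was -0.289 in vector cells and -0.411 in EVI1 cells. Interferon-stimulated genes had a median of 0.13, with 40 of 50 positive and mean responses of 0.335 and 0.468 (adjusted p = 0.000139, and adjusted p = 0.675 with an estimated correlation). Stress response genes had a median of 0.09, with 24 of 30 positive (adjusted p = 0.0411, and adjusted p = 0.883 with an estimated correlation). Without EVI1 ATRA replicate 1, 10 lists passed. All 3 were lost without EVI1 ATRA replicate 3, at adjusted p of 0.153, 0.153 and 0.271. The stress list was lost also without EVI1 ATRA replicate 2 (0.283), EVI1 DMSO replicate 1 (0.498), vector ATRA replicate 3 (0.23) and vector DMSO replicates 1 and 2 (0.189 and 0.182). When arrays rather than genes were permuted, exact p-values of the list means were 0.335, 0.35 and 0.455, and each was 0.455 after adjustment over the 3 lists. That permutation ignores the replicate numbers. Swapping lines within each number and treatment, a test chosen after seeing the data, gave exact p of 0.406, 0.438 and 0.5. Both permutations relabel the lines separately in DMSO and in ATRA, so a line difference of the same sign in both treatments raises p. The mean difference, EVI1 minus vector, was -0.032 in DMSO and -0.154 in ATRA for the MYC list. It was 0.105 and 0.238 for the interferon list, and -0.023 and 0.06 for the stress list. For the MYC and interferon lists these p-values therefore cannot decide whether the responses differ.

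EVI1 against vector cells in DMSO compares the lines before treatment. Osteopontin, the secreted glycoprotein SPP1, was 16.8-fold higher in EVI1 cells (4.07 ± 0.55, adjusted p = 0.0377), PTX3 was higher by 1.81 ± 0.17 (adjusted p = 0.00318) and the repressor BHLHE41 1.86-fold higher (0.90 ± 0.12, adjusted p = 0.0377). The mean of PTX3 in vector cells lay below the 25th percentile of every array, so its difference is a lower bound. F13A1 was lower by -2.06 ± 0.20 (adjusted p = 0.00318) and the focal adhesion protein TNS1 by -0.66 ± 0.09 (adjusted p = 0.0377). These 5 were all the genes that passed, 3 up and 2 down. Each had the 3 EVI1 arrays on the same side of the 3 vector arrays, and each of the 3 same-number pairs had the same sign. The PTX3 and F13A1 calls stood without any single array. SPP1, BHLHE41 and TNS1 each lost theirs without vector DMSO replicate 1, 2 or 3, vector ATRA replicate 1 or 3, EVI1 DMSO replicate 3 or EVI1 ATRA replicate 3, with adjusted p between 0.0545 and 0.21. They lost it, for some of the 3, also without vector ATRA replicate 2, EVI1 DMSO replicate 1 or 2 or EVI1 ATRA replicate 2, with adjusted p between 0.0515 and 0.0792.

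With replicate number as a block, 89 genes passed in DMSO, 72 up and 17 down, and SPP1 had adjusted p = 7.13e-05. Blocked calls included the myeloid membrane protein MS4A3 (-0.99 ± 0.15, adjusted p = 0.0583 unblocked and 0.00637 blocked), PECAM1 (1.01 ± 0.15, 0.0547 and 0.00855), SIGLEC5 (0.71 ± 0.11, 0.0639 and 0.0255), FCER1G (0.96 ± 0.18, 0.0897 and 0.0351), the chemokine receptor CCR2 (-0.84 ± 0.14, 0.0726 and 0.0309), ID2 (0.61 ± 0.10, 0.0754 and 0.0351) and the TGF-beta binding protein LTBP1 (1.24 ± 0.46, 0.531 and 0.00505). Without the block no change was called for ITGAM (0.90 ± 0.28), CD14 (1.01 ± 0.46), CD38 (-0.44 ± 0.14), MYC (-0.27), GATA2 (-0.22), MPO (-0.14), ITGAX (0.30), CEBPE (0.00), DHRS3 (-0.09) or CYP26A1 (-0.13). At an unadjusted p below 0.05 there were 1567 genes, and the unmoderated test called 0. The count without EVI1 ATRA replicate 1 was 36 and without EVI1 DMSO replicate 1 it was 10. It was 3 without EVI1 DMSO or EVI1 ATRA replicate 2, and 2 without vector ATRA replicate 1 or 3, vector DMSO replicate 2 or 3, EVI1 DMSO replicate 3 or EVI1 ATRA replicate 3.

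In DMSO 8 lists passed camera and 0 of these held with an estimated correlation, and 1 of their members, PTX3, was called over all genes. Genes reported as EVI1 targets or partners did not pass (camera adjusted p = 0.503, 0 of 36 called). Higher in EVI1 cells were neutrophil receptors (adjusted p = 0.0211, 3 up adjusted over the list alone, adjusted p = 0.287 with an estimated correlation). Their median was 0.02 and turned to -0.003 with arrays centred on their median or without vector DMSO replicate 3. Secondary granule proteins (0.0171, 3 up adjusted over the list alone, adjusted p = 0.542 with an estimated correlation) and monocyte markers (0.0281, 3 up and 1 down adjusted over the list alone, adjusted p = 0.287 with an estimated correlation) were higher too. So were cell cycle inhibitors (0.00149, 2 up adjusted over the list alone, adjusted p = 0.287 with an estimated correlation), interferon-stimulated genes (0.0126, 1 up, 0.423), chemokines (0.00726, 3 up and 1 down, 0.661) and TGF-beta pathway genes (0.00149, 2 up, 0.145), the last 3 given in the same order of values. The list of primary granule proteins of promyelocytes was lower (0.0256, 3 down adjusted over the list alone, adjusted p = 0.401 with an estimated correlation). That list includes MS4A3, a membrane protein. With the block the myeloid transcription factor and megakaryocyte lists also passed, both at adjusted p = 0.0294. Without the block and with an estimated correlation, camera gave them adjusted p = 0.375 and 0.542. Without EVI1 DMSO replicate 3 the neutrophil (0.178), granule (0.178 for each of both lists), monocyte (0.339), interferon (0.141) and chemokine (0.26) lists were lost. Without EVI1 DMSO replicate 2 the neutrophil (0.0639), secondary granule (0.183), monocyte (0.0617) and chemokine (0.0617) lists were lost, and without vector DMSO replicate 2 the primary granule (0.121), monocyte (0.0672) and interferon (0.0765) lists. The monocyte list was lost without vector DMSO replicate 3 as well (0.0882).

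EVI1 against vector cells in ATRA compares the treated lines. SPP1 was higher in EVI1 cells by 4.45 ± 0.55 (adjusted p = 0.00713), where its mean of 3.48 in vector cells lay below the 25th percentile of every array, so that the size is a lower bound; GDF15 was 10.9-fold higher (3.44 ± 0.35, adjusted p = 0.00478) and CD36 3.34-fold higher (1.74 ± 0.22, adjusted p = 0.00713). MS4A3 was 2.84-fold lower (-1.51 ± 0.15, adjusted p = 0.00478). The actin-binding protein NEXN (-1.12 ± 0.13), the noncoding RNA CCDC26 (-1.08 ± 0.14), the phosphatase PPM1E (-1.01 ± 0.11) and TNS1 (-0.77 ± 0.09) were lower too. PPM1E averaged 3.53 in EVI1 cells, at that background level as well, so that the size of its difference is a lower bound. These 8 calls stood without any single array, and all 3 same-number pairs had the same sign for each. The membrane protein EMP1 (2.70 ± 0.37, adjusted p = 0.0105) and the AP-1 subunit JUN (1.74 ± 0.24, adjusted p = 0.0106) were higher, and both were lost without vector ATRA replicate 1 (0.0647 and 0.0661), vector ATRA replicate 3 (0.0601 and 0.0669) or EVI1 ATRA replicate 3 (0.0561 and 0.0514).

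**Figure D3:**
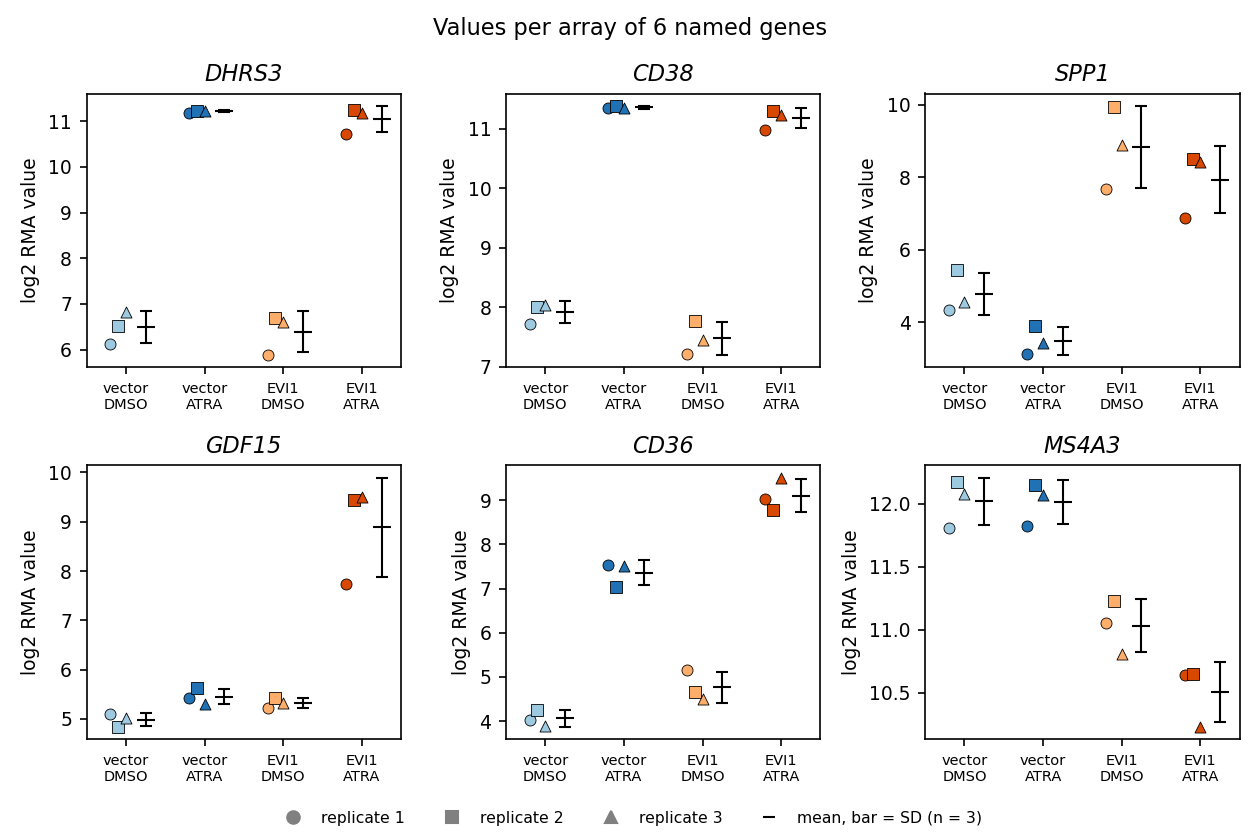
Log2 RMA values (vertical axes) of DHRS3, CD38, SPP1, GDF15, CD36 and MS4A3 on the 12 arrays, with markers for the replicate number and bars for the mean and SD of each group (n = 3). SPP1 averaged 4.77 and 8.84 in vector and EVI1 cells in DMSO, and the mean of DHRS3 in vector cells went from 6.49 in DMSO to 11.22 in ATRA.

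Other genes called in ATRA also depended on single arrays. The galectin LGALS3, the troponin TNNT1, the pterin synthesis enzyme GCH1, the uridine phosphorylase UPP1 and the heme oxygenase HMOX1 were higher by 1.82, 1.76, 1.71, 1.48 and 1.47, at adjusted p of 0.0285, 0.043, 0.0342, 0.0346 and 0.0342. Each was lost without vector ATRA replicate 1, 2 or 3 or EVI1 ATRA replicate 2 or 3 (adjusted p from 0.0554 to 0.193), and some also without EVI1 ATRA replicate 1, EVI1 DMSO replicate 2 or 3 or any vector DMSO replicate (0.0504 to 0.0707). PTPN3, AFF3, DTNA, CCR2 and the nucleotide receptor P2RY2 were lower by -0.94, -0.93, -0.89, -0.82 and -0.77, at adjusted p of 0.0105, 0.0334, 0.0285, 0.0327 and 0.0105. All 5 were lost without vector ATRA replicate 1 or EVI1 ATRA replicate 3 (0.0549 to 0.145), and some also without vector ATRA replicate 2 or 3, EVI1 ATRA replicate 2, EVI1 DMSO replicate 3 or a vector DMSO replicate (0.0505 to 0.146). Of the fixed genes no change was called for ITGAM (0.83), CD14 (1.36 ± 0.46), MYC (-0.46), MPO (-0.27), GATA2 (-0.36), ITGAX (0.52), CD38 (-0.19), CEBPE (-0.14), DHRS3 (-0.16) or CYP26A1 (0.45). In all 94 genes passed, 68 up and 26 down, and 33 differed at least 2-fold, 29 up and 4 down. With replicate number as a block 293 passed, 210 up and 83 down, and by the unmoderated test 12. With the arrays scaled to the housekeeping list the 94 were 57 up and 37 down.

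The count in ATRA moved with single arrays. It was 339 without EVI1 ATRA replicate 1 and 242 without EVI1 DMSO replicate 1. It was 16 without vector ATRA replicate 1 or EVI1 ATRA replicate 3, 21 without vector ATRA replicate 3 and 34 without vector ATRA replicate 2. Without vector DMSO replicate 2 or 3 it was 49 or 60, without EVI1 ATRA replicate 2 it was 50, and without EVI1 DMSO replicate 3 it was 58.

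Of the lists, 10 passed camera in ATRA and 0 held with an estimated correlation. Genes reported as EVI1 targets or partners did not pass (camera adjusted p = 0.611, 1 up and 2 down of 36). Of 29 neutrophil receptors, 3 were higher (5 adjusted over the list alone), with PECAM1 at 1.04 ± 0.15 and the lectin SIGLEC5 at 0.69 ± 0.11, at adjusted p = 5.6e-05 and adjusted p = 0.0573 with an estimated correlation. PECAM1 was lost without any vector ATRA replicate or EVI1 ATRA replicate 2 or 3 (0.0504 to 0.0847), and SIGLEC5 without vector ATRA replicate 1 or 3 or EVI1 ATRA replicate 2 or 3 (0.0504 to 0.142). Of 50 interferon-stimulated genes, 1 was higher (6 adjusted over the list alone), the antiviral factor SAMD9L at 0.78 ± 0.12, with a list median of 0.22, adjusted p = 2.39e-10 and adjusted p = 0.0573 with an estimated correlation. IFI6 had 1.07 ± 0.22 (adjusted p = 0.0643, and 0.0432 with the block). Of 22 cell cycle inhibitors, 2 were higher (6 adjusted over the list alone), with CDKN1A, an inhibitor of cyclin-dependent kinases, at 0.75 ± 0.11 (list adjusted p = 0.00179, and adjusted p = 0.243 with an estimated correlation). SAMD9L and CDKN1A were lost without any vector ATRA replicate or EVI1 ATRA replicate 3 (0.0577 to 0.102). MYC targets and ribosome biogenesis genes had a median of -0.14, with 1 lower of 32 (2 adjusted over the list alone), at adjusted p = 2.14e-07 and adjusted p = 0.372 with an estimated correlation.

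The 6 other lists that passed in ATRA had few or no called members. Retinoid genes (2 higher of 34, 5 up and 1 down adjusted over the list alone) had adjusted p = 0.025 and adjusted p = 0.407 with an estimated correlation, and the 9 NADPH oxidase genes (0 called over all genes or adjusted over the list alone, all 9 positive) had 0.0128 and 0.431 in the same order. Chemokines and NF-kB targets (0 up and 1 down of 37, 4 and 2 adjusted over the list alone) had 0.000734 and 0.508, and TGF-beta pathway genes (1 up of 29, 3 adjusted over the list alone) 0.00194 and 0.0819. Glycolysis and hypoxia genes (0 of 29, 1 up adjusted over the list alone) had 0.00264 and 0.232. The primary granule list was lower (1 of 21, 3 adjusted over the list alone) at 0.0463 and 0.407, and its 1 called member was the membrane protein MS4A3. Without EVI1 ATRA replicate 3 the NADPH oxidase (0.296), chemokine (0.277), primary granule (0.0977) and retinoid (0.215) lists were lost. The retinoid list was lost also without EVI1 ATRA replicate 2 (0.162) or vector ATRA replicate 1 or 2 (0.0721 and 0.0559), and the primary granule list without vector ATRA replicate 2 (0.328), EVI1 ATRA or EVI1 DMSO replicate 1 (0.0689 and 0.0524) or vector DMSO replicate 3 (0.0573). Cholesterol synthesis genes had adjusted p = 0.0564, or 0.0404 with replicate number as a block. Without the block and with an estimated correlation, camera gave them adjusted p = 0.551.

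The EVI1 arrays numbered 1 stood apart from the others of their groups. In DMSO 321 genes and in ATRA 368 genes lay at least 2-fold from both other EVI1 replicates, against 0 to 26 on each of the other 10 arrays. Without both of them, an alternative chosen after seeing the data, 79 genes passed between EVI1 and vector cells in DMSO and 869 in ATRA, 597 up and 272 down, and 3781 and 4029 genes passed for ATRA in vector and EVI1 cells. The same choice raised the number of called members of the chemokine list to 4 up and 1 down in DMSO and 14 up and 2 down in ATRA. For neutrophil receptors it gave 4 up in DMSO and 7 up in ATRA, and for interferon-stimulated genes 1 and 9 up. For monocyte markers it gave 1 up and 1 down in DMSO and 5 up and 2 down in ATRA. For the difference of responses it gave 5 genes, GDF15 (3.63 ± 0.15, adjusted p = 2.73e-06), SLC26A11 (2.32 ± 0.16), CYP1A1 (1.42 ± 0.14), ANKRD6 (1.26 ± 0.16) and JUN (1.02 ± 0.13), of which SLC26A11, CYP1A1 and ANKRD6 were named after their values were seen.

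**Figure D4:**
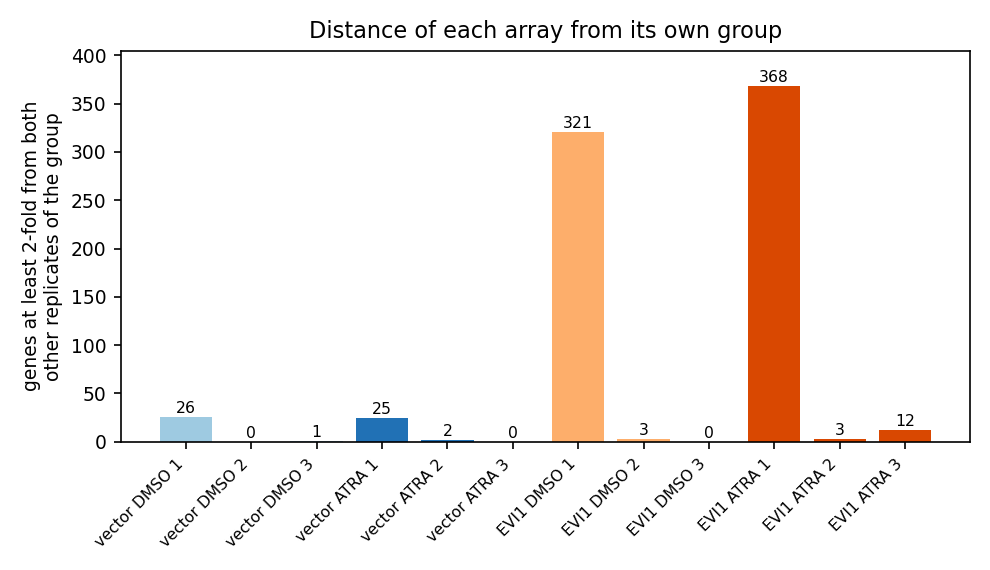
Number of genes (vertical axis) that lay at least 2-fold from both other replicates of the same group, for each of the 12 arrays. The EVI1 arrays of replicate 1 had 321 in DMSO and 368 in ATRA, and the highest of the others had 26.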

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

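The exact permutation tests and the splits of the arrays were chosen before their results were seen, whereas leaving out both EVI1 arrays numbered 1 and swapping lines within replicate numbers were chosen only after the data had been seen.

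In camera 3 lists of genes passed for the difference between the lines in the response to ATRA. The median difference of responses, EVI1 minus vector, was -0.11 for MYC targets and ribosome biogenesis genes, 0.128 for interferon-stimulated genes and 0.0917 for unfolded protein and stress response genes, with 1 of 32, 40 of 50 and 24 of 30 members positive. The tables argue against the explanation that the EVI1 arrays of replicate 1 carried these differences, since without both of them the medians were -0.17, 0.143 and 0.104 and camera's adjusted p was 1.22e-08, 8.47e-05 and 0.00438, although with an estimated correlation it was 0.366, 0.366 and 0.405, past no threshold with these arrays or without, and the stress list was lost without EVI1 DMSO replicate 1 alone (0.498) and not without EVI1 ATRA replicate 1 alone. That EVI1 changes the response of these lists stays open. List means had the same direction in all 3 replicate numbers, but permuting arrays gave exact p of 0.335, 0.35 and 0.455. That permutation ignores the replicate numbers and had low power for the share of genes in simulated data. Swapping the lines within each replicate number and treatment gave exact p of 0.406, 0.438 and 0.5 over 64 arrangements. Both permutations relabel the lines separately in each treatment, so a line difference of the same sign in DMSO and ATRA raises p. The MYC and interferon lists had such a difference, so for them these p-values cannot decide the question. Camera's calls were lost with an estimated correlation (adjusted p of 0.675, 0.675 and 0.883) and without EVI1 ATRA replicate 3 (0.153, 0.153 and 0.271). Variation between cultures that moves all members of a list together may therefore account for them as well.

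Probe sets without a single gene name responded to ATRA too. Of 13522 such probe sets, 58 changed at least 2-fold with adjusted p under 0.05 in vector cells, 47 up and 11 down, and 64 did so in EVI1 cells, 54 up and 10 down, where each was set against the DMSO arrays of the same line. For the difference of responses 0 of them passed by limma, as for the named genes.

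Other splits of the arrays were counted for each comparison. For each comparison of 3 with 3 arrays the 6 arrays make 10 splits, too few for a share under 0.05. Every other split mixes both groups, so the difference between them widens the spread within each part. A count of 0 from such splits is close to given in advance. The real split gave 2029 genes for ATRA in vector cells, 2437 for ATRA in EVI1 cells, 5 for EVI1 in DMSO and 94 for EVI1 in ATRA, and in each the highest of the others gave 0, including the others among the 4 splits that part all 3 same-number pairs; the real split was the 1 that gave as many. For the difference of responses, the real count was 0, so 100 of 100 splits gave at least as many by construction and the count says nothing about chance; the highest other split gave 1.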

How the results depend on the processing

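No call of a named gene turned its sign, and no call of a list its test direction: of 7097 alternatives run on 255 values of named genes, 6606 kept their side of the threshold, 283 lost the call and 208 gained one, and of 2565 run on 135 list tests 2410, 96 and 59 did. Values that were not called turned sign in 48 alternatives for genes and 162 for list medians. Of called lists, the median of the apoptosis list in EVI1 cells under ATRA went from 0.17 to -0.02 without EVI1 DMSO replicate 2, and that of neutrophil receptors for EVI1 in DMSO from 0.02 to -0.003 with arrays centred or without vector DMSO replicate 3. Of 143 calls of named genes 93 stood in every alternative, and of 42 calls of lists 2 did. Settings that leave out both EVI1 arrays numbered 1, all 4 arrays numbered 1 or the 20 genes higher in vector replicate 1, and culture as a random block, were chosen after seeing the data. Except where fewer arrays or genes make the change by construction, the cause was not tested. Probe sets near background limit what can be seen: genes below the median level, such as MECOM, give no value under that filter, and no depth applies to arrays. Scaling left the median log2 difference of all genes between -0.0529 and 0.

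Counts that moved more than 1.5 times were the following. ATRA in vector cells (2029) gave 4079 with array weights, 3522 with only the groups compared, 3781 without both EVI1 arrays numbered 1, 3772 without them and with the replicate block, and 3176 with culture as a random block. ATRA in EVI1 cells (2437) gave 824 with only the groups compared, 4029 without both EVI1 arrays numbered 1, 4058 without them and with the replicate block, and 3729 without the 4 arrays numbered 1. The difference of responses (0) gave 2 with array weights, and 5, 3 and 7 in these last 3 settings. The overlap (1616) gave 2713 with array weights, 782 with only the groups compared, 2784 without both EVI1 arrays numbered 1 and 2796 with the replicate block as well.

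EVI1 in DMSO (5) gave 2 with the mean of all probe sets, with every probe set tested and with only the groups compared, 0 with genes above the median and by the unmoderated test, 9 after a further quantile normalization, 16 with an intensity trend and robust prior, 70 with array weights, 8 with culture as a random block, 79 without both EVI1 arrays numbered 1, 138 without them and with the replicate block, and 147 without the 4 arrays numbered 1. EVI1 in ATRA (94) gave 483 with array weights, 49 with only the groups compared, 12 by the unmoderated test, 869 without both EVI1 arrays numbered 1, 793 without them and with the replicate block, and 489 without the 4 arrays numbered 1. With the replicate block alone EVI1 in DMSO gave 89 and EVI1 in ATRA 293; the block also brought 17 calls of named genes and 4 of lists past the threshold and changed no other call.

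The share of responsive genes with the larger response in EVI1 cells (0.515 as a fraction, 51.5%) fell to 0.398 with genes chosen in vector cells (exact p = 0.755), 0.5 with genes above the median (exact p = 1) and 0.498 with housekeeping scaling (exact p = 0.98). Choosing genes by their vector response favours those whose vector response is overestimated, which by itself lowers the share. Some alternatives raised the share. It was 0.704 without both EVI1 arrays numbered 1 (exact p = 0.51) and 0.646 without the 4 arrays numbered 1 (exact p = 0.556). Leaving out single arrays gave 0.357 to 0.732, with 0.479 and 0.456 without vector DMSO and vector ATRA replicate 1 and 0.454 without EVI1 ATRA replicate 2. With an estimated correlation the lists past the threshold went from 11 to 0 for ATRA in vector cells, 10 to 2 for ATRA in EVI1 cells, 3 to 0 for the difference, 8 to 0 for EVI1 in DMSO and 10 to 0 for EVI1 in ATRA. They were 6 for the difference without both EVI1 arrays numbered 1 and 14 for EVI1 in DMSO without the 4 arrays numbered 1.

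Leaving out each array in turn, which leaves 2 arrays in a group, gave 1070 to 2690 genes for ATRA in vector cells, 1513 to 3434 for ATRA in EVI1 cells, 0 to 3 for the difference, 2 to 36 for EVI1 in DMSO, 16 to 339 for EVI1 in ATRA and 972 to 2101 for the overlap. It gave 10 to 12, 9 to 11, 0 to 10, 2 to 9 and 6 to 14 lists in the same order of contrasts, and a MECOM difference of 0.03 to 0.12 in DMSO and -0.13 to 0.02 in ATRA.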

Other observations

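All tests of the EVI1 arrays numbered 1, and the genes named in this part that the rule for naming genes does not name, were chosen only after the values were seen.

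The 8 genes of this paragraph up to TNFAIP6 were picked because they were higher in EVI1 cells than in vector cells in replicates 2 and 3 by more than in replicate 1. CD14, the lipopolysaccharide coreceptor, differed in log2 by 0.10 in replicate 1 and by 1.43 or more in replicates 2 and 3 in DMSO, and in ATRA by 0.12 in replicate 1 and by up to 2.45 in the others. The calprotectin subunits S100A8 and S100A9 differed in DMSO in the 3 replicate numbers by -0.06, 1.39 and 1.94 and by 0.34, 1.55 and 1.58, and the chemokine CCL2 by -0.40, 1.84 and 2.09. In ATRA the cytokine IL1B differed by -0.07, 1.71 and 2.65, the endosomal RNA sensor TLR8 by -0.41, 1.43 and 2.47, the neutrophil chemokine CXCL8 by -0.38, 1.34 and 1.26 and the hyaluronan-binding TNFAIP6 by -0.27, 2.10 and 2.57. Over all 3 replicates 0 of these passed in limma in the contrasts given, with CD14 at adjusted p = 0.63 in DMSO and 0.27 in ATRA, and since they were picked for this pattern no test of it was made on them. Not all monocyte genes went this way: the chemokine receptor CCR2 differed in DMSO by -1.25, -0.56 and -0.70, and the list of monocyte and macrophage markers passed camera upward in DMSO (adjusted p = 0.0281, and adjusted p = 0.287 with an estimated correlation) but not in ATRA (0.153).

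Another set of genes marked replicate 1 in both lines. It held the 20 genes that were at least 2-fold higher in replicate 1 than in replicates 2 and 3 of vector cells in both treatments, among them the mitochondrial aminotransferase OAT, the stem cell homeobox factor MEIS1, the receptor CD93, the calcium-binding S100P and the glycoprotein GPNMB. Relative to EVI1 DMSO replicate 1, their level was 102% in EVI1 ATRA replicate 1, 14.8% and 13.2% in vector replicate 1 in DMSO and ATRA, 13.5% to 22.8% in the other EVI1 arrays and 3.83% to 4.27% in the other vector arrays. In these last arrays 4 of the 20 genes averaged below the 25th percentile of every array, so their shares are upper limits. OAT, for example, was higher in EVI1 cells by 3.04, 3.52 and 4.23 in DMSO in the 3 replicate numbers, with adjusted p = 0.464 without the replicate block and 8.06e-05 with it (3.60 ± 0.25, SE). In ATRA its difference was 3.49 ± 0.25 with the block, with adjusted p = 0.265 without it and 0.000101 with it. With the block 17 of the 20 genes in DMSO and 19 in ATRA were called higher in EVI1 cells by limma, and without it 0 were in either. The 20 genes were chosen for differing between replicate numbers, and the block removes that variation. The gain in calls with the block, for OAT as for the set, therefore follows largely from the choice of genes.

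The EVI1 arrays of replicate 1 lay at least 2-fold from both other EVI1 replicates for 321 genes in DMSO and 368 in ATRA. Against the mean of EVI1 replicates 2 and 3, 174 genes were at least 2-fold higher and 70 at least 2-fold lower in both treatments. The tables argue against a swap of an EVI1 and a vector sample, since genes called from replicates 2 and 3 went the same way in replicate 1 for 81.1% of 53 in DMSO and 78.7% of 122 in ATRA. A second cell population in different shares may account for the 20 genes: they lay 6.75-fold and 7.19-fold higher in EVI1 than in vector replicate 1, and the SD of their log2 ratio lay at percentile 0.09 of random sets in DMSO and 5.34 in ATRA, which leaves it open. RNA degradation stays open too, with a 3′ minus 5′ difference of vector replicate 1 against vector replicates 2 and 3 of -0.17 for ACTB (SD 0.0947) and -0.0125 for GAPDH (SD 0.0222), while the EVI1 arrays of replicate 1 had the 2 highest GAPDH differences of the 12 arrays, 0.35 and 0.32 against a mean of 0.232 in vector replicates 2 and 3, and ACTB differences of 1.58, the highest, and 1.37. The GAPDH difference was higher in EVI1 than in vector cells in every same-number pair. In DMSO it was 0.35, 0.23 and 0.24 against 0.25, 0.22 and 0.21, and in ATRA 0.32, 0.26 and 0.3 against 0.19, 0.24 and 0.26. The ACTB difference was not always higher (1.24 against 1.35 in DMSO replicate 3). Whether this moved the comparisons between the lines was not tested. A difference between separately kept EVI1 cultures, which the labels do not describe, was not tested either.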
